A study of Mus musculus with 12 samples.

How the data were processed

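RNA from mouse lung was measured by sequencing in 12 libraries, 3 each of Control and CKO at P14 and at P36. Per the labels, RNA was extracted with miRNeasy and libraries were made from 100 ng of total RNA with KAPA RNA HyperPrep. The authors checked reads with FastQC, aligned them with STAR to mm10 and counted them per gene with featureCounts; the versions of these tools are not given in the sources used here. The deposited count table holds counts of reads per gene for 24421 genes, with the coordinates of each gene. The deposited table named CPM holds log2 values for 15458 genes, which were checked to match log2 CPM with TMM scaling and a prior count of 2 to within 5e-09. Of the tested genes, 15320 matched a GENCODE M21 name and 15304 of these (99.9%) overlapped its mm10 coordinates.

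Library depth was 17806206 to 28481876 counts. The ribosomal RNA gene Rn45s took 0.867% to 2.23% of the counts and the 10 most abundant genes 8.91% to 11.2%. The exact intervals given for genes with few counts cover counting error only.

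Groups followed the labels of genotype and age. Genes were tested in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood F-test (filterByExpr by group with a minimum count of 10 and total of 15, TMM, robust dispersion) in a single fit of all 12 libraries. The threshold was an adjusted p (Benjamini-Hochberg over 15923 genes) under 0.05. The 6 comparisons were CKO with Control at P14, at P36 and averaged over both ages, the difference of the genotype effect between P36 and P14, and P36 with P14 in Control and in CKO. An error after ± is a standard error on log2 fold changes and a standard deviation on CPM. CPM were counts scaled to the library total over tested genes, adjusted by the TMM factors.

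Fixed gene lists of pathways and cell types with at least 5 tested members, 64 in all, were tested by camera in limma 3.58.1 on log2 CPM with the preset correlation of 0.01, and again with the correlation estimated for each list. The count "adjusted over the list alone" applied the Benjamini-Hochberg method to the members of a list only. A list score is the mean difference in log2 CPM of its members from the mean of all libraries.

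Named genes followed a fixed rule. In each comparison these were the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM in a group compared and no overlap between the groups, at any age used. Tbx4 was reported apart and predicted gene models were left out. Members of the lists with the smallest p, up to 4 for each list, were named beside them. These comparisons, lists, rules and most alternatives were chosen before the data were examined.

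The alternatives were no filter, a filter of 1 CPM in 3 libraries, scaling by library totals or relative log expression, DESeq2 1.42.0, limma-voom, limma trend on the deposited log2 values, dispersion without the robust option, a fold threshold of 1.2, 1 surrogate variable from sva 3.50.0, a replicate block, only the groups compared, each library left out in turn, a term for sex, and libraries of a shared number summed. The lists were also tested with fry. Sex was read from counts, as Y-linked genes above or below Xist. Libraries that shared a number were counted apart in the main test, as the labels list them. They differed by more than sampling of a single library (mean chi-square 2.03 and 3.76 over genes with at least 50 counts), which does not show that they come from separate animals, so each result was repeated with them summed. The method was tested on simulated data, with 200 genes changed in counts drawn from the fitted model, and on other splits of the libraries.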

Results

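RNA was sequenced from mouse lungs at postnatal days 14 and 36 (P14 and P36). Animals were labelled Control, with Tbx4 alleles flanked by loxP sites, or CKO, a conditional knockout of Tbx4. Tbx4 encodes a T-box transcription factor of the embryonic lung mesenchyme. The Cre driver of the knockout is not given in the sources used here. The title of the series names the questions, which are what loss of Tbx4 does to the lung after birth and whether it favours pulmonary hypertension. Each of the 4 groups held 3 libraries, 12 in all. Their depth ran from 17806206 to 28481876 counts. Nothing in the labels states that the libraries come from separate animals, so the p-values measure the spread between these samples.

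The libraries held structure beyond genotype and age. Control replicates 1 and 3 at P36 shared a library number, and so did CKO replicates 2 and 3 at P14. These pairs had biological coefficients of variation of 2.02% and 3.89%, against 10.6% to 27.5% in the other 10 pairs within a group. Xist, the RNA that coats the inactive X chromosome, exceeded the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in all 6 P14 libraries and in Control replicates 1 and 3 at P36. Y-linked counts were the higher ones in Control replicate 2 and in all 3 CKO libraries at P36, so sex partly followed genotype at that age. The first principal component of the 500 most variable genes (40.4% of the variance) had P14 libraries at -31.9 to -12.9 and P36 libraries at 4.42 to 29.0. Its 5 largest loadings were Xist and these 4 Y-linked genes, so sex went into it along with age. The second (28.7%) set CKO P36 replicate 3 apart at -41.4. In that library the adipose marker list lay 3.05 and the club cell marker list 2.60 log2 units above the mean of all libraries. Adipoq, the fat cell hormone adiponectin, stood at 60.6 CPM there and Bpifa1, a secreted airway protein, at 198 CPM, against at most 7.13 and 6.43 CPM in any other library. Both genes were chosen after their values were seen. Cardiac muscle markers lay 1.91 and 1.43 log2 units above that mean in Control P14 replicates 2 and 3, and at -1.44 in replicate 1.

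Tbx4 itself did not differ past the threshold between CKO and Control, with a lower mean in CKO at P14 and a higher mean at P36. At P14 Tbx4 (chromosome 11, 85890063 to 85916097, build mm10) stood at 134 ± 23.2 CPM in Control and 121 ± 8.93 CPM in CKO (mean ± SD, n = 3 each). At P36 the levels were 69.0 ± 9.39 CPM in Control and 79.2 ± 10.6 CPM in CKO. The fold change of CKO over Control was 0.904 at P14 (95% confidence interval 0.731 to 1.12, adjusted p = 0.626) and 1.15 at P36 (0.926 to 1.42, adjusted p = 0.511). Averaged over both ages the log2 fold change was 0.03 ± 0.10 (SE, adjusted p = 0.949). With a term for sex the log2 fold change was -0.012 at P36 and -0.079 averaged. Tbx4 fell with age, by 0.95 ± 0.14 on the log2 scale in Control (adjusted p = 0.000379) and by 0.61 ± 0.14 in CKO (adjusted p = 0.00989). Sex went with age in CKO, where the fall did not pass with libraries summed and a term for sex (-0.95, adjusted p = 0.157). The count file gives 1 total per gene, so RNA that lacks a deleted exon was counted with the rest. Tbx4 therefore does not check the labels, and each direction of the genotype effect below rests on them.

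**Figure D1:**
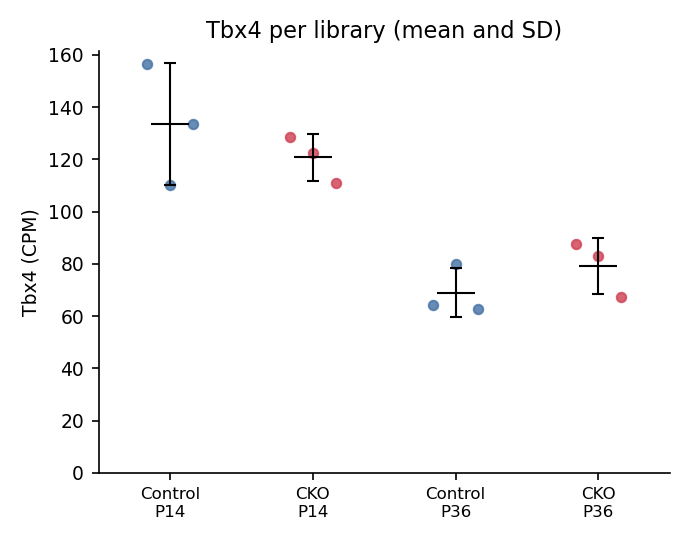
Tbx4 in CPM (counts scaled to the library total with TMM factors, vertical axis) in each library, by group (horizontal axis). Blue points are Control libraries, red points are libraries labelled CKO, and black marks give the mean and SD of 3 libraries, with means of 134 and 121 CPM at P14 and 69.0 and 79.2 CPM at P36.

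At P14, when alveoli are forming, the comparison of CKO with Control asked which lung genes the genotype changed. In the libraries labelled CKO, 8 of 10 genes of MHC class II antigen presentation, 8 of 16 dendritic cell markers and 9 of 19 complement genes rose, and 5 of 20 alveolar fibroblast markers fell. Camera called these lists with its preset correlation only (adjusted p = 0.239, 0.239, 0.323 and 0.682 with an estimated correlation). Ccl11 (eotaxin, a chemokine that attracts eosinophils) stood at 2.39 ± 0.966 CPM in Control and 19.2 ± 2.33 CPM in CKO (SD, n = 3 each), a log2 fold change of 3.01 ± 0.24 (SE, adjusted p = 0.000223). Dcx, the microtubule-binding doublecortin of migrating neurons, stood at 1.55 ± 0.356 CPM in Control and 24.2 ± 4.04 CPM in CKO, a log2 fold change of 3.96 ± 0.33 (adjusted p = 0.000223). Of 15923 genes tested, 531 rose and 177 fell, and 210 of these changed at least 2-fold. In each gene named for its large change here and below, the libraries of the groups compared did not overlap. Among the other large rises were Lrrtm3, a synaptic adhesion protein (3.33 ± 0.41), Otof, the otoferlin of hair cell synapses (3.16 ± 0.26), Cd207, the langerin of Langerhans cells (2.66 ± 0.43), and Tlr11, a Toll-like receptor (2.57 ± 0.33), with adjusted p from 0.000223 to 0.00576. The protease inhibitor gene Serpina3f rose by 2.80, Shisa3 by 2.70, Ano5, an anoctamin, by 2.59 and Prmt8, an arginine methyltransferase, by 2.58. The largest falls were Wfdc16 (-3.94 ± 0.77, adjusted p = 0.0158), Megf11 (-3.71), A2m, the protease inhibitor alpha-2-macroglobulin (-3.62), and Nxf7 (-3.29). Sez6l (-3.19), Colq, the collagen tail of acetylcholinesterase (-3.10), Crabp1, which binds retinoic acid (-3.04), Syt6, a synaptotagmin (-3.02), Gsg1l (-2.89) and Fam151a (-2.85) also fell. Counting libraries of a shared number once left 128 of the 708 genes, with 7 of the 10 rises named here and 1 of the 10 falls, Sez6l, among them. Adding a term for sex to this left 6 and 1 of them. The count was 253 without CKO replicate 2, 231 without CKO replicate 3, 364 without Control replicate 2 and 379 without Control replicate 3.

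Several lists of immune genes were called higher at P14, and B and plasma cell markers lower. Of 10 genes of MHC class II presentation, 8 rose (8 adjusted over the list alone), with H2-Aa at 1.32, H2-Ab1 at 1.43 and Ciita, the transactivator of the class, at 1.13 (camera adjusted p = 1.17e-10 for the list, adjusted p = 0.239 with an estimated correlation). H2-Aa went from 122 ± 18.6 CPM to 306 ± 53.3 CPM (SD, n = 3 each). Of 16 dendritic cell markers, 8 rose and none fell (10 rose and 1 fell adjusted over the list alone), led by Xcr1 at 2.54 and Clec9a at 2.35, receptors of cross-presenting dendritic cells (4.31e-08, adjusted p = 0.239 with an estimated correlation). Complement had 9 of 19 members higher (13 adjusted over the list alone), among them the protease gene C1s1 at 1.09, the inhibitor gene Serping1 at 0.75 and the receptor gene C3ar1 at 0.70 (1.70e-09, adjusted p = 0.323 with an estimated correlation). Of 16 markers of natural killer and innate lymphoid cells, 6 rose (11 adjusted over the list alone), with Il1rl1, the receptor of interleukin-33, at 1.2 and Tbx21, a T-box factor of these cells, at 1.59 (3.55e-06, adjusted p = 0.214 with an estimated correlation). Monocyte markers split, with 4 of 14 up and 1 down (6 and 1 adjusted over the list alone). Ccr2, the receptor that brings monocytes out of the marrow, rose by 1.63 (adjusted p = 2.2e-05) and Fn1, fibronectin, fell by 0.72 on the log2 scale (0.00131 for the list, adjusted p = 0.379 with an estimated correlation). Of 18 interstitial macrophage markers 6 rose (7 adjusted over the list alone), among them Mgl2 at 1.13 and Mrc1 at 0.71, both lectins, and Gas6 at 0.50 (6.85e-05, adjusted p = 0.323 with an estimated correlation). Cytokines and chemokines had 5 of 23 members higher (9 adjusted over the list alone), with Csf1, the macrophage growth factor, at 0.40 and Ccl22 at 1.2 beside Ccl11 (7.67e-05, adjusted p = 0.214 with an estimated correlation). Of 14 B and plasma cell markers 0 passed in edgeR (0 adjusted over the list alone), and their median was -0.33 (0.0046, adjusted p = 0.67 with an estimated correlation). Each of these medians kept its sign with library totals alone as the scaling. With libraries of a shared number summed Serping1, C3ar1, Tbx21, Fn1, Mrc1, Gas6 and Ccl22 no longer passed.

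In epithelial, mesenchymal and signalling lists at P14 some members rose and others fell. Of 17 markers of alveolar type 2 cells, which make surfactant, 2 rose (6 adjusted over the list alone), Lyz2, a lysozyme, by 0.83 and Sftpa1, surfactant protein A, by 0.69 (3.92e-06 for the list, adjusted p = 0.536 with an estimated correlation). Of 20 alveolar fibroblast markers 5 fell and 1 rose (8 and 2 adjusted over the list alone). Scube2, a secreted carrier of Hedgehog ligand, fell by 1.5, Slc7a10, an amino acid transporter, fell by 1.18, and Inmt, a methyltransferase, rose by 1.23 (0.0404, adjusted p = 0.682 with an estimated correlation). Among 20 genes of elastic fibre assembly 4 rose and 1 fell (8 and 1 adjusted over the list alone). The crosslinking enzyme genes Loxl1 and Loxl2 rose by 0.63 and 0.45, and Mfap4, a microfibril-associated protein, fell by 1.11 (0.000393, adjusted p = 0.374 with an estimated correlation). Of 19 genes of TGF-beta signalling 4 rose (5 adjusted over the list alone), with the receptor gene Tgfbr1 at 0.35 and the ligand gene Tgfb3 at 0.83 (0.000228, adjusted p = 0.27 with an estimated correlation). BMP signalling, tied to pulmonary hypertension through its receptor, had 5 of 29 members up and 2 down (6 and 2 adjusted over the list alone), with the ligand genes Bmp2 at 1.0 and Bmp5 at 0.96 and the BMP-binding protein gene Bmper at -1.59 (0.341, adjusted p = 0.769 with an estimated correlation). With libraries of a shared number summed only Scube2, Bmp5 and Bmper still passed of the genes named in this paragraph. Camera called 26 of 64 lists at P14, 18 up and 8 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.214.

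**Figure D2:**
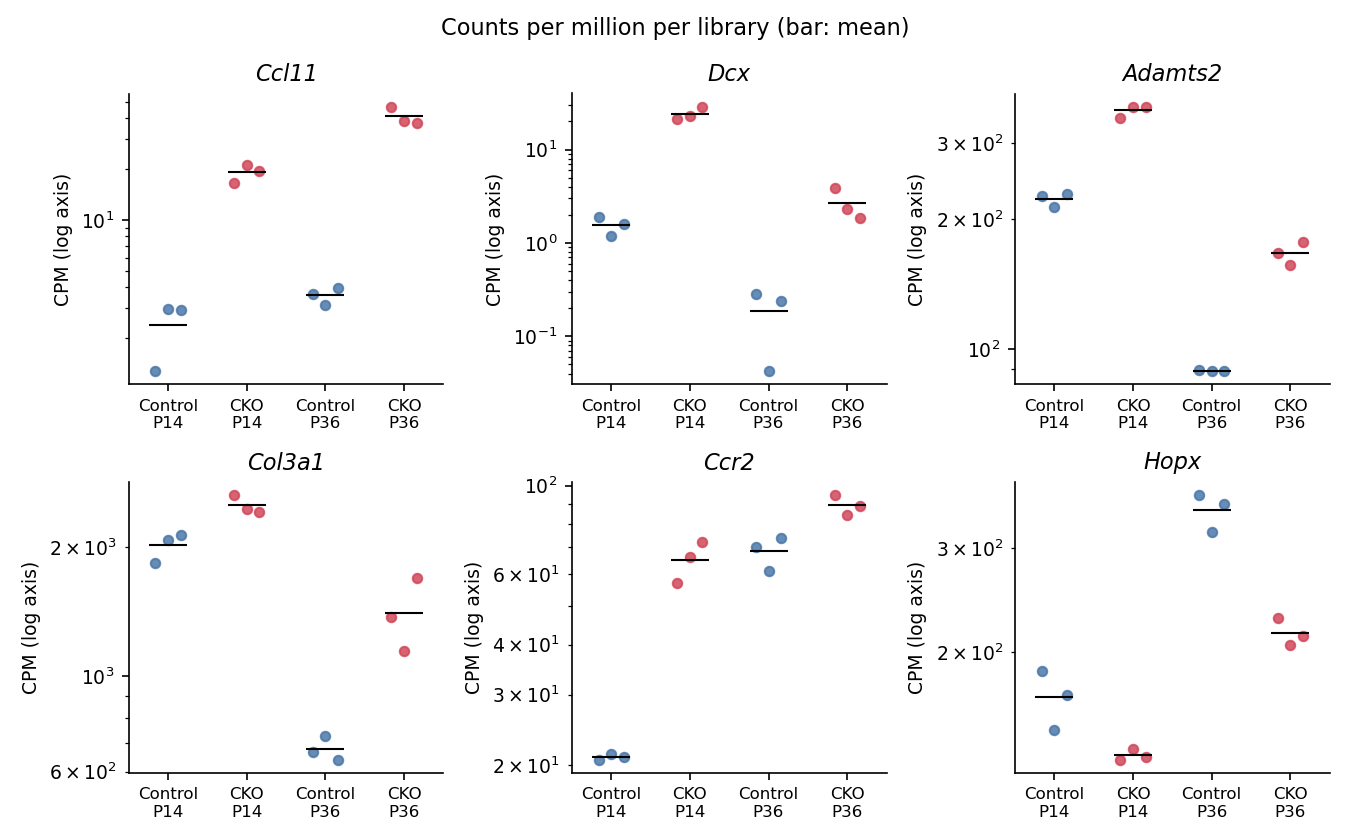
CPM (vertical axes, logarithmic) of 6 named genes in each library by group, with Control in blue, CKO in red and the mean of 3 libraries as a bar. Ccl11, Dcx and Adamts2 of the libraries labelled CKO lay above each Control library of the same age.

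At P36, after most alveoli have formed, CKO was again set against Control. In the libraries labelled CKO, 10 of 24 genes of fibrillar collagen and 6 of 20 of elastic fibres rose, and 2 of 14 markers of alveolar type 1 cells, the flat cells of gas exchange, fell. Camera called these lists with its preset correlation only (adjusted p = 0.198, 0.198 and 0.307 with an estimated correlation), and with a term for sex 1, 1 and 0 of their genes passed in edgeR. Ccl11 rose again, from 3.59 ± 0.423 CPM in Control to 41.1 ± 5.05 CPM in CKO (SD, n = 3 each), a log2 fold change of 3.51 ± 0.23 (SE, adjusted p = 4.78e-05). Of 15923 genes 237 rose and 134 fell, and 110 of these 371 changed at least 2-fold. Dcx (3.74 ± 0.44) and Lrrtm3 (4.10 ± 0.50) rose at this age too. Grik3, a kainate receptor subunit, had 2 counts over the Control libraries and 156 over the CKO libraries, 94.9 times as many per total count (exact 95% interval 25.8 to 791, adjusted p = 0.00113). Kcnj5, a potassium channel (3.11), Kctd16 (2.93), Fbln7, a fibulin (2.66), Tdo2, a tryptophan dioxygenase (2.65), Col28a1, a collagen (2.56), and Fhl5 (2.55) were the other large rises, with adjusted p from 0.00206 to 0.0473. Cpne4, a copine, had 82 counts in Control and 2 in CKO (ratio 33.7, exact 95% interval 9.03 to 283). Has1, a hyaluronan synthase (-2.57 ± 0.45), Slc13a4, a sulfate transporter (-2.43 ± 0.28), Ndst4, a heparan sulfate enzyme (-2.11), Cntn1, the adhesion protein contactin (-2.01), and Unc5d, a netrin receptor (-1.70), fell. So did Adgrf2 (-1.63), Prkg2, a kinase driven by cyclic GMP (-1.45), Col6a5, a collagen VI chain (-1.41), and Bmper (-1.41). With a term for sex 38 genes passed, 30 of them among the 371, and 370 of the 371 kept their sign, while counting libraries of a shared number once left 42. Of the 10 rises and 10 falls named here 5 and 4 passed in the latter, 3 and 4 with the term for sex, and 0 and 0 in edgeR with both, where 1 gene in all passed. With the term for sex Has1 moved to -1.33 and Tdo2 to 1.87 on the log2 scale, while Dcx moved to 5.80 and Grik3 to 8.74. That term sets the CKO libraries against Control replicate 2 alone, the only Y-high Control library. Dcx stood at 0.0425 CPM there and Grik3 had 2 counts over the Control libraries. The values of Dcx and Grik3 with the term therefore rest on very few counts. The count was 222 without CKO replicate 1, 177 without CKO replicate 2, 82 without Control replicate 1, 101 without Control replicate 3 and 612 without Control replicate 2.

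Camera called matrix lists higher at P36 and the alveolar type 1 list lower. Of 24 genes of fibrillar collagens and their processing 10 rose (15 rose and 2 fell adjusted over the list alone). Adamts2, the protease that trims procollagen, rose by 0.91 ± 0.06 (adjusted p = 4.8e-05), Col3a1 by 1.05 and Col5a1 by 0.91 (camera adjusted p = 9.51e-10 for the list, adjusted p = 0.198 with an estimated correlation). Col3a1 stood at 678 ± 44.1 CPM in Control and 1406 ± 273 CPM in CKO (SD, n = 3 each). Of 20 genes of elastic fibre assembly 6 rose (15 adjusted over the list alone), with Eln, elastin, at 1.36, Fbln2, a fibulin, at 0.99 and Loxl2 at 0.80 (2.78e-09, adjusted p = 0.198 with an estimated correlation). Markers of adventitial fibroblasts, the cells around vessels and airways, moved with these lists, with 4 of 18 higher, Ccl11 among them, and 1 lower, Has1 (7 and 1 adjusted over the list alone, 0.00824, adjusted p = 0.693 with an estimated correlation). Their list score was -0.06 to 0.49 in CKO and -0.46 to -0.11 in Control at P36, and 0.21 to 0.28 and -0.60 to 0.05 at P14. At P14 2 of the 18 rose (2 adjusted over the list alone, 0.00662, adjusted p = 0.604 with an estimated correlation). All 14 alveolar type 1 markers had a negative fold change, also with library totals alone in the median (-0.48). Of these 2 fell (13 adjusted over the list alone), Hopx, a homeodomain protein, by 0.69 ± 0.08 (adjusted p = 0.0021) and Gprc5a, a membrane receptor, by 0.62 on the log2 scale (1.23e-11, adjusted p = 0.307 with an estimated correlation). Of 20 alveolar fibroblast markers 3 fell (3 adjusted over the list alone), Nebl (-0.49), Scube2 (-1.16) and Tcf21, a transcription factor of lung mesenchyme (-0.79), with 0.000278 for the list and adjusted p = 0.604 with an estimated correlation. Of 20 smooth muscle markers 1 rose (9 adjusted over the list alone), Lmod1, a leiomodin, by 0.90 (9.92e-06, adjusted p = 0.594 with an estimated correlation). The mean over the smooth muscle list was 0.73 in CKO replicate 3, the library with high adipose and club cell markers, against -0.28 and -0.21 in the other CKO libraries and -0.53 to -0.42 in Control. Lmod1 passed without CKO replicate 1 and not without any other single P36 library (0.70, adjusted p = 0.0715, without CKO replicate 3). Pericyte markers had 2 of 17 members higher (9 adjusted over the list alone), Abcc9, a potassium channel subunit, at 1.19 and Notch3 at 0.62 (0.000105, adjusted p = 0.594 with an estimated correlation). Hedgehog signalling had 2 of 13 members higher (5 adjusted over the list alone), the transcription factor gene Gli3 at 0.44 among them (3.22e-05, adjusted p = 0.0809 with an estimated correlation). Of 22 genes of cholesterol synthesis 2 fell (8 adjusted over the list alone), Msmo1 (-0.43) among them, with 2.5e-07 for the list and adjusted p = 0.594 with an estimated correlation. Of 17 alveolar type 2 markers 0 passed in edgeR (3 fell adjusted over the list alone), and the median was -0.35, or -0.13 with the sex term (4.66e-06, adjusted p = 0.632 with an estimated correlation). Camera called 18 lists, 9 up and 9 down, 11 of them also with a term for sex, under which the medians of 2 turned sign, and 0 with an estimated correlation, where the smallest adjusted p was 0.0809. The median of the type 1 markers was -0.51, and -0.46 with the sex term. Of the list members named here only Adamts2, Fbln2 and Ccl11 passed with the sex term.

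**Figure D3:**
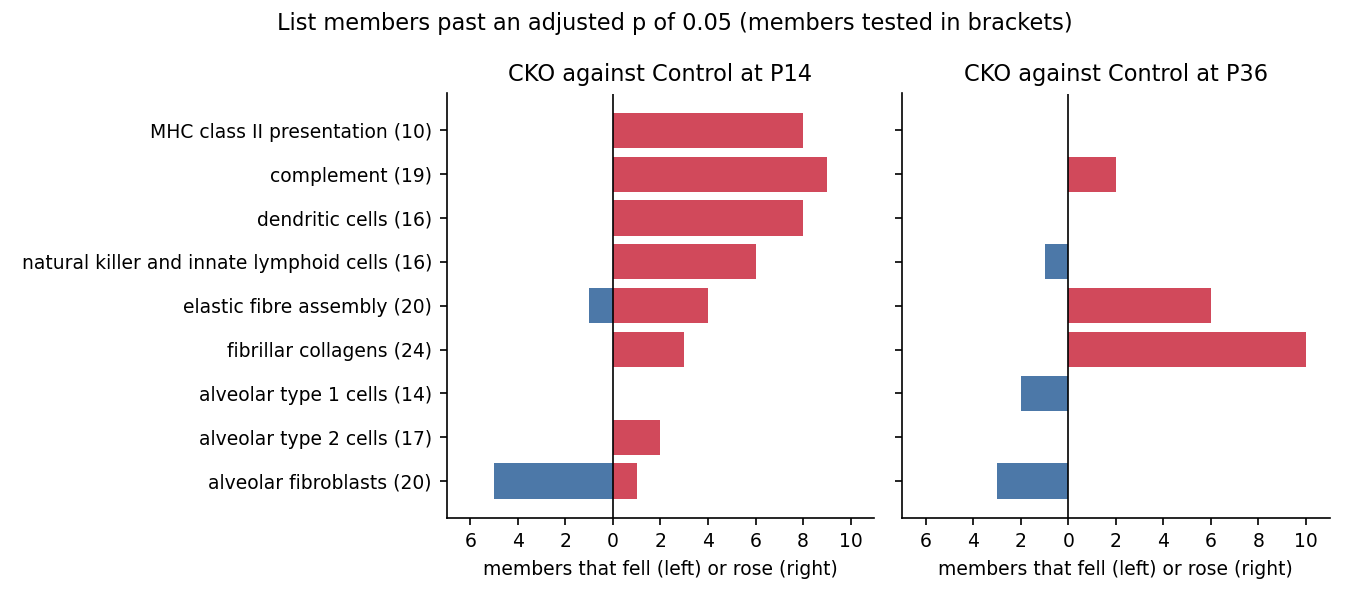
Members of 9 gene lists past an adjusted p of 0.05 in CKO against Control at P14 (left panel) and P36 (right panel), with bars to the right (red) for members that rose and to the left (blue) for members that fell. At P14, 8 of 10 MHC class II genes rose, and at P36, 10 of 24 collagen genes rose.

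Averaging the genotype effect over both ages asked what the libraries labelled CKO had in common. Ccl11, Dcx and the procollagen protease gene Adamts2 rose at each age. In the average 10 of 20 elastic fibre genes rose and 6 of 20 alveolar fibroblast markers fell, in lists that camera called with its preset correlation only (adjusted p = 0.167 and 0.422 with an estimated correlation). Of 15923 genes 509 rose and 206 fell, and 149 of these 715 changed at least 2-fold. Ccl11 rose by 3.26 ± 0.17 (SE, adjusted p = 3.14e-06) and Adamts2 by 0.79 ± 0.04 (adjusted p = 2.6e-06). Dcx (3.85), Lrrtm3 (3.72), Chodl, chondrolectin (3.06), Tpsb2, a mast cell tryptase (2.83), Gdf6, a BMP-family ligand (2.73), Ano5 (2.55), Otof (2.54), Tdo2 (2.40) and Shisa3 (2.36) completed the large rises. The large falls were Wfdc16 (-3.16), Nxf7 (-2.61), Colq (-2.57), Syt6 (-2.52), A2m (-2.48), Scrg1 (-2.45), Ndst4 (-2.36), Gsg1l (-2.34), the sodium leak channel gene Unc80 (-2.21) and Slc13a4 (-2.07). At P14 and P36 alike 71 genes rose, against 7.90 for independent lists (Fisher's exact test, p = 3.67e-48), and 20 fell, against 1.49 (p = 3.01e-17), while 4 changed in opposite directions. These p-values take genes as independent of one another and measure no spread between libraries. With libraries of a shared number counted once 14 rose and 2 fell at both ages. At P36 18 of the 91 still passed with a term for sex, and all 91 kept their sign. Over all genes the fold changes at the 2 ages had a Pearson r of -0.06 and a Spearman rho of -0.11, a correlation across genes, which are not independent replicates. With libraries of a shared number counted once 236 of the 715 genes passed, and the count was 409 without CKO P14 replicate 2, 383 without CKO P14 replicate 3, 446 without Control P36 replicate 1 and 435 without Control P36 replicate 3. With a term for sex 468 passed, 376 of them among the 715. Of the 10 rises and 10 falls named here 7 and 8 passed with libraries of a shared number counted once, 8 and 9 with the term for sex, and 6 and 4 with both.

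In the average over both ages, 10 of 20 genes of elastic fibre assembly rose and 1 fell (13 and 1 adjusted over the list alone), with Loxl2 at 0.63, Fbln1 at 0.92 and Fbn1, fibrillin, at 0.51 (camera adjusted p = 6.6e-11, adjusted p = 0.167 with an estimated correlation). Of 24 fibrillar collagen genes 8 rose (11 adjusted over the list alone), with Col3a1 at 0.68 and Col12a1 at 0.54 (1.42e-08, adjusted p = 0.214 with an estimated correlation). Of 14 alveolar type 1 markers 6 fell (13 adjusted over the list alone), among them Hopx (-0.51), Gprc5a (-0.40) and Rtkn2 (-0.26), with 6.6e-11 for the list and adjusted p = 0.214 with an estimated correlation. At P36 the list scores did not overlap (-0.07 to -0.01 in CKO, 0.43 to 0.51 in Control). At P14 the scores overlapped (-0.38 to -0.16 in CKO, -0.40 to 0.04 in Control) and 0 of the 14 passed in edgeR (1 fell adjusted over the list alone, 0.0162, adjusted p = 0.675 with an estimated correlation). Of 20 alveolar fibroblast markers 6 fell (8 fell and 2 rose adjusted over the list alone), with Scube2 at -1.33, Slc7a10 at -0.83 and Tcf21 at -0.65 (0.000286, adjusted p = 0.422 with an estimated correlation). TGF-beta signalling had 4 of 19 members higher (9 adjusted over the list alone), Tgfb3 at 0.88 and its target Pmepa1 at 0.48 among them (0.000165, adjusted p = 0.214 with an estimated correlation). BMP signalling had 4 of 29 up and 2 down (6 and 3 adjusted over the list alone), with Bmper at -1.5, Bmp5 at 0.85 and Bmp4 at 0.35 (0.172, adjusted p = 0.72 with an estimated correlation). Lymphatic endothelial markers had 4 of 10 higher (5 rose and 1 fell adjusted over the list alone), with the extracellular proteins Mmrn1 at 0.45 and Reln, reelin, at 0.49 (0.0157, adjusted p = 0.341 with an estimated correlation). Mast cell, basophil and eosinophil markers had 2 of 8 higher (4 adjusted over the list alone), the proteases Tpsb2 at 2.83 and Cpa3 at 2.15 (0.00903, adjusted p = 0.341 with an estimated correlation). Tpsb2 was not called in 9 of 26 alternatives and Cpa3 in 12 of 26, summed libraries among them for both and the sex term for Cpa3. Fbn1, Col12a1, Tcf21 and Reln no longer passed with either, and Rtkn2 with libraries summed. Camera called 25 of 64 lists, 18 up and 7 down, 16 of them also with a term for sex, under which the median of 1 turned sign, and 0 with an estimated correlation, where the smallest adjusted p was 0.167.

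The difference of the genotype effect between P36 and P14 asked whether age changed the response. Among the 256 genes that passed, some of antigen presentation, innate lymphoid cells and surfactant had a more negative effect at P36 than at P14, and the imprinted noncoding RNA genes Meg3 and Rian a more positive one. None of these genes passed with libraries of a shared number counted once or with a term for sex, and the smallest adjusted p of a list was 0.308 with an estimated correlation. Serpina3f had the largest difference, -4.42 ± 0.59 (SE, adjusted p = 0.0212), with 1.23 ± 0.165 CPM in Control and 8.56 ± 4.0 CPM in CKO at P14, and 8.99 ± 0.557 CPM and 2.92 ± 1.39 CPM at P36 (SD, n = 3 each). Meg3 went the other way, from 107 ± 20 CPM in Control and 58.8 ± 9.85 CPM in CKO at P14 to 15.4 ± 3.52 CPM and 35.9 ± 11 CPM at P36, a difference of 2.10. Of 15923 genes 73 had a more positive effect at P36 and 183 a more negative one. Of 10 MHC class II genes 4 had a more negative effect (9 adjusted over the list alone), H2-Aa at -1.16 and H2-Ob at -0.83 among them (camera adjusted p = 7.27e-08, adjusted p = 0.441 with an estimated correlation). Of 16 natural killer and innate lymphoid markers 3 were more negative (11 adjusted over the list alone), with Klrb1c, an activating receptor, at -1.54 and Rora at -0.49 beside Areg (2.69e-06, adjusted p = 0.308 with an estimated correlation). Alveolar type 2 markers had 2 of 17 more negative (13 adjusted over the list alone), Sftpa1 at -1.21 and Lyz2 at -1.10 (4.98e-09, adjusted p = 0.441 with an estimated correlation). Alveolar macrophage markers had 5 of 18 more negative (6 adjusted over the list alone), with Atp6v0d2, a proton pump subunit, at -1.14 and Siglecf at -1.08 beside Chil3 (0.000445, adjusted p = 0.441 with an estimated correlation). The monocyte list had 1 of 14 more negative, Ccr2 at -1.25 (6 more negative and 1 more positive adjusted over the list alone, 0.0213, adjusted p = 0.51 with an estimated correlation). Of 24 collagen genes 2 had a more positive effect (10, and 2 more negative, adjusted over the list alone), Col5a1 at 0.98 and Col6a3 at 0.76 (0.000749, adjusted p = 0.441 with an estimated correlation). The calls of the 256 genes ended under 2 alternatives: 0 passed in edgeR with libraries of a shared number counted once (2028 at an unadjusted p under 0.05) and 0 with a term for sex (2250 at an unadjusted p under 0.05), against 3393 at that level here, with 1055 past the threshold in DESeq2 and 97 in limma-voom. The folds moved less than the calls, since all 256 kept their sign in both, with a median of 0.962 and 0.895 of the reported difference. These genes were picked by their difference in the same libraries, so kept signs and folds lend that difference no further support. Serpina3f stood at -4.27 (adjusted p = 0.256) and -4.52 (0.158), and Meg3 at 1.93 (0.257) and 1.76 (0.205). The count was 0 without CKO P14 replicate 2, CKO P36 replicate 2 or Control P36 replicate 1 or 3, and 1, 6, 27 and 108 without CKO P14 replicate 3, Control P14 replicates 3 and 2 and CKO P36 replicate 3. It was 426, 483 and 732 without Control P14 replicate 1, CKO P14 replicate 1 and Control P36 replicate 2. The share of more positive genes was 28.5% with TMM and 46.5% with library totals alone (80 and 92 of 172 genes).

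**Figure D4:**
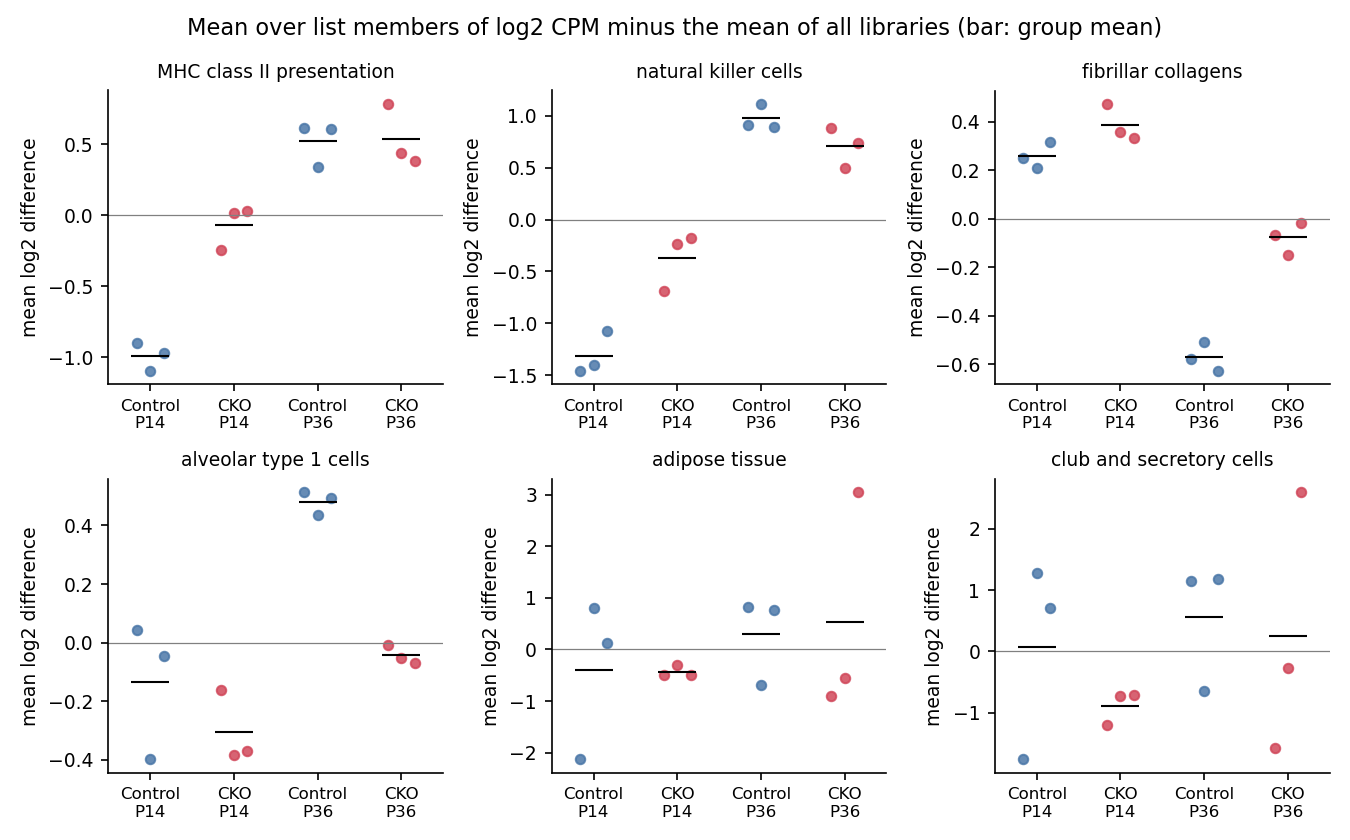
Mean log2 difference from all libraries over the members of 6 gene lists (vertical axes) in each library by group, with Control in blue, CKO in red and the group mean as a bar. The MHC class II mean ran from -1.10 to -0.90 in Control and from -0.25 to 0.03 in CKO at P14, and adipose and club cell markers reached 3.05 and 2.60 in CKO P36 replicate 3.

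Control lungs at P36 against P14 showed how the ages differed in these libraries. Library numbers of P14 and P36 formed separate ranges, in Control and CKO alike. Age was thus not told apart from whatever those numbers follow. Genes of cholesterol synthesis, surfactant and lymphocytes were higher at P36, and genes of cell division, collagen and elastin were lower. Camera called these lists with its preset correlation only (adjusted p from 0.0906 to 0.287 with an estimated correlation). Eln, elastin, fell from 4426 ± 629 CPM to 414 ± 147 CPM (SD, n = 3 each), a log2 fold change of -3.42 (adjusted p = 6.5e-06). Of 15923 genes 3346 rose and 3333 fell, and 1668 changed at least 2-fold. Cyp1a1, a cytochrome of xenobiotic metabolism, had 2 counts at P14 and 618 at P36 (ratio 238, exact 95% interval 65.7 to 1973). Klra9, a natural killer cell receptor, had 0 counts at P14 and 83 at P36, at least 21.3-fold higher against a floor of 3 counts over the group. Klrc2, a receptor of the same cells, had 3 and 107 counts (ratio 27.5, exact 95% interval 9.17 to 136). The cytotoxic granule genes Prf1 (4.49 ± 0.46), Gzma (4.55) and Gzmb (4.70), Tex11, a meiosis gene (4.6), the anion exchanger gene Slc26a3 (4.55), Tat, tyrosine aminotransferase (4.41), and Gdf2, the endothelial ligand BMP9 (3.93), also rose. Nell1 had 143 counts at P14 and 2 at P36 (ratio 92.7, exact 95% interval 25.2 to 773). The other large falls were Camk1g, a calcium-dependent kinase (-5.31 ± 0.45), Crabp1 (-5.16), Trim67 (-4.95), Lrrc10, a cardiac protein (-4.70), Kctd16 (-4.19), Mansc4 (-4.07), Cacna1g, a calcium channel (-3.89), the metalloprotease gene Adamts17 (-3.84) and Thbs2, thrombospondin-2 (-3.72). Lrrc10 stood at 1.83 ± 1.47 CPM (SD) at P14, where the fixed cardiac muscle markers were high in Control replicates 2 and 3. The count was 4552 with libraries of a shared number counted once, and the 10 rises and 10 falls named here passed in it.

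Many members of several lists moved with age in Control. Of 22 genes of cholesterol synthesis 21 rose (21 adjusted over the list alone), with Insig1 at 1.48 and Msmo1 at 1.44 (camera adjusted p = 2.95e-11, adjusted p = 0.241 with an estimated correlation). All 17 alveolar type 2 markers rose (17 adjusted over the list alone), with Lyz2 at 1.73 and Sftpb, surfactant protein B, at 1.25 (8e-09, adjusted p = 0.287 with an estimated correlation). All 17 T cell markers (17 adjusted over the list alone) and all 10 MHC class II genes (10 adjusted over the list alone) rose, with Cd2 at 1.61 and H2-Ob at 1.87 (8e-09 and 1.31e-07, adjusted p = 0.212 and 0.241 with an estimated correlation). Of 16 natural killer and innate lymphoid markers 13 rose (13 adjusted over the list alone), with Ncr1 at 3.62 and Klre1 at 3.5 (1.99e-07, adjusted p = 0.0906 with an estimated correlation). Of 14 alveolar type 1 markers 10 rose (11 adjusted over the list alone), Hopx by 1.05 (6.3e-05, adjusted p = 0.327 with an estimated correlation). Of 26 genes of the G2 and M phases of the cell cycle 25 fell (25 adjusted over the list alone), with Ccna2, cyclin A, at -1.47 and Mki67 at -1.04 (7.34e-11, adjusted p = 0.241 with an estimated correlation). Of 24 fibrillar collagen genes 17 fell (17 fell and 1 rose adjusted over the list alone), with Adamts2 at -1.32 and Col5a1 at -1.83 (6.79e-08, adjusted p = 0.212 with an estimated correlation). Elastic fibre assembly had 13 of 20 lower and 3 higher (14 and 3 adjusted over the list alone), with Loxl2 at -1.24 and Fbn2 at -2.22 (0.000207, adjusted p = 0.266 with an estimated correlation). Markers of secondary crest myofibroblasts, the cells that lay elastin in forming septa, had 13 of 19 lower (13 adjusted over the list alone), Aspn, asporin, at -2.44 (0.000125, adjusted p = 0.241 with an estimated correlation). Basement membrane genes had 16 of 23 lower (18 adjusted over the list alone), the laminin gene Lama4 at -1.01 and the nidogen gene Nid2 at -1.70 (2.88e-06, adjusted p = 0.311 with an estimated correlation). Camera called 28 of 64 lists, 18 up and 10 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.0906.

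The same age comparison in CKO asked how lungs labelled CKO differed between the ages. The lists of cholesterol synthesis, T cells and cell division were called in the same directions as in Control (adjusted p = 0.302, 0.302 and 0.403 with an estimated correlation). Insig1, which restrains sterol synthesis, rose from 38.5 ± 3.17 CPM to 86.0 ± 5.14 CPM (SD, n = 3 each), a log2 fold change of 1.16 (adjusted p = 1.1e-05). Of 15923 genes 2283 rose and 2105 fell, and 889 changed at least 2-fold. All 3 CKO P36 libraries were Y-high and all 3 CKO P14 libraries Xist-high, so sex and age went together within CKO. Y-linked Uty had 2 counts at P14 and 7656 at P36 (ratio 3484, exact 95% interval 964 to 28770), and Xist changed by -12.54. The next largest rises were Cyp2a5, a cytochrome (6.58 ± 2.02, adjusted p = 0.041), Cyp1a1 (5.70 ± 0.46), Ppp2r2c, a phosphatase subunit (5.24), Jchain, the joining chain of polymeric antibodies (4.12), Olfm2 (4.05), Pigr, which carries these antibodies across epithelium (4.04), and Spink5, a protease inhibitor (3.93). Cyp2a5 was not called in 12 of 21 alternatives, and stood at 2.57 (adjusted p = 0.172) without CKO P36 replicate 3, the library set apart above. Spink5 was not called in 12 of 20, that library left out among them. Mdga2 had 3 counts at P14 and 75 at P36 (ratio 22.7, exact 95% interval 7.49 to 113), and Rnase1, a secreted ribonuclease, had 3 and 71 (ratio 21.5, exact 95% interval 7.08 to 107). Camk1g (-4.23 ± 0.44), Lrrc15 (-4.12), the olfactory receptor gene Olfr1034 (-3.58), Trim67 (-3.58), Npy2r, a receptor of neuropeptide Y (-3.39), Mansc4 (-3.29), Dcx (-3.17), Egfem1 (-2.95) and Agt, angiotensinogen (-2.91), fell. With a term for sex, taken from the Control P36 libraries, 2056 genes passed, 1689 of them among the 4388, and Npy2r turned positive. For Dcx that term rested on 0.0425 CPM in Control P36 replicate 2 against 0.283 and 0.242 CPM in replicates 1 and 3. Such low levels cannot tell sex from age in the fall of Dcx. Dcx went to -0.70 (adjusted p = 0.837) with that term, Agt to -1.68 (0.234), Rnase1 to 2.14 (0.264), Olfm2 to 2.24 (0.0866) and Ppp2r2c to 3.07 (0.0258). Of the 10 rises and 10 falls named here 3 and 2 passed in it, 7 and 9 with libraries of a shared number counted once, and 1 and 0 with both. The count was 2152 with libraries of a shared number counted once and 2490 without CKO P14 replicate 3.

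Of the lists in CKO, 20 of 22 genes of cholesterol synthesis rose with age (20 adjusted over the list alone), with Fdft1, squalene synthase, at 1.16 and Lss at 1.08 (camera adjusted p = 6.1e-12, adjusted p = 0.302 with an estimated correlation). Of 17 T cell markers 14 rose (16 adjusted over the list alone), Cd2 by 0.86 (5.9e-07, adjusted p = 0.302 with an estimated correlation). Of 14 B and plasma cell markers 11 rose (12 adjusted over the list alone), with the complement receptor gene Cr2 at 2.01 and Cd22 at 1.2 (7.18e-07, adjusted p = 0.403 with an estimated correlation). Of 10 MHC class II genes 5 rose (8 adjusted over the list alone), H2-Ob by 1.04 (0.000607, adjusted p = 0.467 with an estimated correlation). Ciliated cell markers had 11 of 20 higher (17 adjusted over the list alone), Tppp3 at 0.68 and Dynlrb2 at 1.38 (6.37e-05, adjusted p = 0.625 with an estimated correlation). Their list score was -0.51, 0.45 and 1.0 in CKO P36 replicates 1, 2 and 3 and -0.73 to -0.64 at P14, so this rise was largest in the library with high club cell markers and small in replicate 1. Alveolar type 2 markers had 7 of 17 higher (8 adjusted over the list alone), Sftpb at 0.65 (0.00204, adjusted p = 0.625 with an estimated correlation), and alveolar type 1 markers 5 of 14 (5 adjusted over the list alone), Hopx at 0.69 (0.0343, adjusted p = 0.709 with an estimated correlation). Of 26 genes of the G2 and M phases 13 fell (17 adjusted over the list alone), with Ccna2 at -0.75 and Top2a at -0.71 (7.18e-07, adjusted p = 0.403 with an estimated correlation). Of 24 fibrillar collagen genes 17 fell (17 fell and 1 rose adjusted over the list alone), with Adamts2 at -1.10 and Col5a2 at -0.91 (2.25e-07, adjusted p = 0.302 with an estimated correlation). Elastic fibre assembly had 10 of 20 lower and 3 higher (11 and 3 adjusted over the list alone), Eln at -2.48 (0.000537, adjusted p = 0.403 with an estimated correlation). Camera called 29 of 64 lists, 18 up and 11 down, 22 of them also with a term for sex, under which the median of 1 turned sign, and 0 with an estimated correlation, where the smallest adjusted p was 0.302. The test of the difference between these age effects is the one given above for the genotype effect at the 2 ages.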

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

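The splits of the 12 libraries and the test of sex on genes past the threshold at P36 and not at P14 were planned; the splits of summed libraries and the remaining tests in this part were chosen after the results were seen.

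The genotype effect differed between P36 and P14 in 256 genes and 24 lists by the test of that difference. Of 100 splits of the libraries, drawn at random within each age, 2 gave as many genes as the real one, itself included. Such splits test for no genotype effect at either age. They therefore cannot exclude chance for a difference of that effect between the ages. The highest other split gave 715 and is the real genotype contrast averaged over the ages, a structure of the libraries. The real split keeps libraries of a shared number together. With them summed 0 genes passed, a count that all 100 splits reach whatever they hold (highest other 51), so the summed splits decide nothing about chance. For the lists 22 of 100 splits gave as many, with 29 in the highest other, so chance was not excluded.

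The effect was more positive at P36 in Meg3 (a difference of 2.10, from -0.87 at P14 to 1.23 at P36), Csmd1 (1.90), Cacna2d3, a calcium channel subunit (1.81), Rnft2 (1.80), Mdga1 (1.75), Rian, which lies with Meg3 in an imprinted cluster (1.61, from -0.85 to 0.76), and Kif18b, a mitotic kinesin (1.59). Jph2, a junctophilin of muscle (1.49), Wbscr17 (1.47) and the ribosomal protein gene Rpl29 (1.18) were the others of the 10 largest. It was more negative in Serpina3f (-4.42, from 2.80 to -1.62), Areg, the growth factor amphiregulin (-2.61, from 1.21 to -1.40), Col6a5 (-2.20, from 0.80 to -1.41), Gpr82 (-2.17), Serpina3g (-2.0) and Chil3, a chitinase-like protein of alveolar macrophages (-1.93, from 1.04 to -0.89). Gcsam (-1.85), Xcr1 (-1.70, from 2.54 to 0.84), Ms4a6c (-1.67) and Clec9a (-1.66, from 2.35 to 0.69) completed the 10 most negative. Adjusted p of these genes ran from 0.0212 to 0.0484, and no gene had one under 0.256 with libraries of a shared number summed or under 0.158 with a term for sex.

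The genes past the threshold at P36 were weighed against sex, since all 3 CKO libraries and 1 of the 3 Control libraries at that age were Y-high. For the 91 genes that changed in the same direction at both ages sex is argued against for the change at P14 alone, because 0 of the 6 P14 libraries were Y-high. With a term for sex all 91 kept their sign at P36, but most no longer passed. A part of sex in their change at P36 was therefore not excluded. For genes past the threshold at P36 alone, the Control library of the same sex as CKO was left out and the fit repeated. It called 612 genes, a set other than the 371 reported, and 514 of them did not pass at P14. Over these the left-out library had a median position of 0.524 between the other Control libraries (0) and CKO (1), with quartiles of 0.278 and 0.768, so sex and genotype cannot be told apart for these genes, with 1 library to decide. A genotype effect stays open as well.

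The rise of MHC class II and dendritic cell genes at P14 was weighed against lymph node, thymus or blood carried with the lung. Against 1.16 for dendritic cell markers, the median was -0.33 for B and plasma cells, 0.29 for T cells, 0.13 for thymus and immature T cells, 0.022 for erythroid cells and -0.44 for platelets and megakaryocytes. These values argue against each of the 3 tissues as the whole cause. For blood this rests mainly on the B cell, T cell and platelet lists. Only 9 of the 18 erythroid markers were tested, and haemoglobin genes had no counts or were absent. A single animal behind CKO replicates 2 and 3 was weighed too. CKO replicate 1, of another number, had a mean over the MHC class II list 0.65 above the highest Control library, which argues against that animal as the whole cause. An effect of the genotype on these cells, or on their genes within cells, may underlie the rise and stays a hypothesis.

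The count of Tbx4 in CKO, not past the threshold as lower, was weighed against a swap of labels. The lowest Control library stood at 0.847 of the mean of its age and the lowest CKO library at 0.873, so the level marks no library as a knockout and a swap cannot be told apart from right labels. An excised exon that leaves the rest of the transcript counted cannot be told apart from an intact gene, since the file holds 1 total for Tbx4, and counts per exon were not analysed here. Recombination in few of the cells that express Tbx4 was not tested.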

How the results depend on the processing

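Alternatives that sum libraries with a term for sex, the term for sex on lists, the sum of libraries for shared genes, the replicate block within genotype and, for Tbx4, all but scaling, the other tests, the replicate block and libraries left out were chosen after seeing the data. Libraries left out apart, 179 of 229 alternatives kept the direction and the side of the threshold, or a count within 1.5 times the reported one, and 50 did not. The 179 include the fit without haemoglobin and mitochondrial genes, which could not differ, and Tbx4 values that stayed short of the threshold. They also include the term for sex at P14, where all libraries were Xist-high and the folds could hardly move. Where a change is given below, the cause was not tested.

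Counts of genes (reported 708 at P14, 371 at P36, 715 averaged, 256 for the difference, 6679 for age in Control and 4388 for age in CKO) moved with several choices. With libraries of a shared number summed they were 128, 42, 236 and 0 for the genotype and 2152 for age in CKO. With a term for sex they were 38 at P36, 468 averaged, 0 for the difference and 2056 for age in CKO. With both they were 66, 1, 114, 0, 3366 and 49 in the order above. A fold threshold of 1.2 left 253, 98, 221, 2, 3600 and 1479. DESeq2 gave 1105 at P14, 853 at P36 and 1055 for the difference, and 1 surrogate variable 788 at P36, 1112 averaged and 514 for the difference. Fitting only the groups compared gave 208 at P36. For the difference, no filter gave 155 and limma-voom 97. In edgeR the counts of 0 for the difference stood beside 2028 genes (summed), 2250 (sex) and 1331 (both) at an unadjusted p under 0.05.

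Leaving out each library in turn gave 231 to 755 genes at P14 (lowest without CKO P14 replicate 3), 82 to 612 at P36 (lowest without Control replicate 1, highest without Control replicate 2), 383 to 847 averaged and 0 to 732 for the difference. It gave 5016 to 6673 for age in Control and 2490 to 4263 for age in CKO. Lists numbered 21 to 31 at P14, 18 to 25 at P36, 21 to 31 averaged, 22 to 30 for the difference, 28 to 34 for age in Control and 26 to 32 for age in CKO.

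With an estimated correlation camera called 0 lists in each of the 6 comparisons, at adjusted p of at least 0.0809, while fry called 14 at P14, 4 at P36, 16 averaged, 3 for the difference, 37 for age in Control and 27 for age in CKO. With a term for sex 25 of the 26 lists at P14 stayed called, 11 of 18 at P36, 16 of 25 averaged, 21 of 24 for the difference, 28 of 28 for age in Control and 22 of 29 for age in CKO. All P14 libraries were Xist-high, so at P14 the term had no difference in sex to correct and its result there is uninformative. A simulated list of 20 members changed 1.5-fold was called under either correlation. Its genes were drawn independently, so this does not show what the test with an estimated correlation finds among correlated genes.

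Tbx4 at P36 turned from 0.20 to -0.012 with a term for sex and to -0.017 with libraries summed as well, and averaged over the ages from 0.027 to -0.079 and -0.069. Without a library it ran from -0.26 to -0.014 at P14, 0.11 to 0.32 at P36, -0.030 to 0.093 averaged and 0.21 to 0.46 for the difference. The averaged value turned negative without CKO P36 replicate 1 (-0.015), Control P14 replicate 2 (-0.030) or Control P36 replicate 3 (-0.0030). For age it ran from -1.07 to -0.82 in Control and -0.70 to -0.50 in CKO. The difference passed with 1 surrogate variable (0.52, adjusted p = 0.0433, 0.10 to 0.52 over all alternatives), and age in CKO no longer passed with libraries summed and a term for sex (-0.95, adjusted p = 0.157).

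Genes shared by the ages numbered 91, and 154 at an adjusted p under 0.10, 456 at an unadjusted p under 0.05 and 16 with libraries summed. Genes that changed in opposite directions were counted apart for each direction. They numbered 27 and 5 at an adjusted p under 0.10, and 237 and 121 at an unadjusted p under 0.05. The first component held 43.1% of the variance over all genes. Of the named genes, 4 values turned, all for age in CKO: Xist to 0.63 with the term for sex and 0.62 with libraries summed as well, and Npy2r to 1.37 and 1.52. Deviations from the group mean in Control and CKO libraries of the same replicate number correlated at 0.085 to 0.198 at P14. At P36 they correlated at -0.280 to 0.336. Pairs of unlike number ran from -0.156 to 0.112 at P14 and -0.391 to 0.369 at P36. Pairing was not tested. A replicate block gave 664, 386, 666 and 255 genes for the genotype and, within genotype, 5795 and 3021 for age. The alternative without haemoglobin and mitochondrial genes changed no count, since these genes had no counts or were absent. In simulated data the test recovered 44.8% of genes changed 1.5-fold at P14, 77.6% of those changed 2-fold and 93.9% of those changed 4-fold, and 29.9%, 49.3% and 92.4% for the difference. Of the genes called there 7.10% at P14 and 9.63% for the difference were false, above the nominal 5%, with 0.637% to 6.75% in the other comparisons. The simulated libraries were drawn independently, with no pairs of a shared number and no effect of sex, and genes of low expression were left unchanged. Each comparison had a single draw. These rates therefore do not describe the real libraries. Without a library the lone other members of a group were assumed to vary like the rest.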

Other observations

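The splits of the 12 libraries and the tests of lungs lying towards another age were planned, and the splits of summed libraries and the test of genes near Tbx4 were chosen after the results were seen.

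Genes of the circadian clock moved in both directions with age. In Control 6 of 19 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.581, adjusted p = 0.887 with an estimated correlation), and in CKO 5 rose and 7 fell (5 and 9 adjusted over the list alone, 0.44, adjusted p = 0.834 with an estimated correlation). Nr1d1, a repressor of the clock that peaks by day in mice, went from 35.2 ± 9.69 CPM at P14 to 324 ± 7.33 CPM at P36 in Control (SD, n = 3 each) and from 29.5 ± 1.22 CPM to 366 ± 40.2 CPM in CKO. Npas2, an activator of the clock, fell by 2.12 in Control, and Cry1, a repressor, fell by 1.44 in CKO. The hour of collection is not given in the sources used here.

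Few genes tied to pulmonary arterial hypertension in people passed the threshold by genotype, which does not show that the rest stayed unchanged. Of 20 tested, 0 rose and 1 fell at P14 (1 adjusted over the list alone), and 0 passed at P36 in edgeR (0 adjusted over the list alone), with camera adjusted p of 0.951 and 0.848 and adjusted p = 0.986 and 0.966 with an estimated correlation. With age in Control 5 rose and 5 fell (5 and 6 adjusted over the list alone), among them Gdf2 at 3.93, the potassium channel gene Kcnk3 at -1.18 and Sox17, a factor of endothelium, at -0.61 (0.863, adjusted p = 0.973 with an estimated correlation). Of 7 T-box genes 4 fell with age in Control (4 adjusted over the list alone), Tbx4, Tbx2 (-0.88), Tbx5 (-1.06) and Tbx20, a factor of heart (-3.45), with 0.0411 for the list and adjusted p = 0.25 with an estimated correlation. The T-box list score in Control at P14 was 0.62 and 0.55 in replicates 2 and 3, the libraries with high cardiac muscle markers (1.91 and 1.43), and -0.10 in replicate 1 (-1.44), so heart tissue and age were not told apart in Tbx20. In CKO 3 fell, Tbx4, Tbx5 (-0.45) and Tbx2 (-0.35), and at P14 and P36 0 passed by genotype in edgeR.

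Other splits of the libraries were counted for each comparison. Averaged over the ages 1 of 100 splits gave as many genes as the real 715, the real one itself, with 256 in the highest other. These splits take libraries of a shared number as separate. With them summed 2 of 100 splits gave as many as the real 236, a share under 0.05. This does not exclude a grouping of the libraries other than genotype, since the other of the 2 gave more genes. The other of the 2 gave 347 and set Control P14 replicates 2 and 3, CKO P36 replicates 2 and 3 and the summed Control P36 library against the rest, which points to a structure of the libraries other than genotype. For its 25 lists 18 of 100 gave as many, with 34 in the highest other, so chance was not excluded. Within a single age or genotype there are 10 splits, too few for a share under 0.05. The real split gave 708 genes at P14 (highest other 0), 371 at P36 (90), 6679 for age in Control (0) and 4388 for age in CKO (0), and in each 1 of 10 splits reached the real count. The lists numbered 26 at P14 (highest other 24, 1 of 10 splits as many), 18 at P36 (28, 7 of 10), 28 for age in Control (37, 7 of 10) and 29 for age in CKO (27, 1 of 10). The split of 90 genes at P36 set CKO replicate 3 with Control replicates 1 and 3, the libraries with the highest adipose and club cell markers at that age. It also parts 3 Y-high libraries from the 2 Xist-high ones, which share a number, so tissue content, sex and the shared number were not told apart in it.

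A hypothesis was that CKO lungs at P14 lie towards the older lungs. Across 15380 autosomal genes the genotype effect and the age effect in Control had a Pearson r across genes of 0.0759, 0.168 and 0.226 and a Spearman rho of 0.149, 0.150 and 0.181 with each Control P14 library in turn as the baseline of the genotype effect and the others as that of the age effect. The bound set beforehand was 0.1, with no coefficient named. The rho values all lay above it and the lowest r below it, which leaves the hypothesis undecided.

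A further hypothesis was that CKO lungs at P36 lie towards the younger lungs. With the Control library of the same sex as baseline the Pearson r across genes was -0.161 and the Spearman rho -0.0887, and with the other Control libraries -0.366 and -0.421. All 4 values were negative, but the rho with the library of the same sex stopped short of the -0.1 set beforehand, which leaves this hypothesis undecided too.

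Another hypothesis was that DNA flanking the targeted allele, carried along from another strain, changed genes near Tbx4. Within 10 Mb of Tbx4 on chromosome 11, 8 of 244 genes (3.28%) passed in the average over both ages, against 4.51% of other genes (Fisher's exact test, p = 0.437). At P14 11 of the 244 (4.51%) passed, against 4.45% of other genes (Fisher's exact test, p = 0.876). At P36 4 of the 244 (1.64%) passed, against 2.34% (Fisher's exact test, p = 0.667). No share differed past a p of 0.05 in either direction, which leaves the hypothesis open.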
